A study of Homo sapiens with 6 samples.

How the data were processed

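MDA-MB-231 cells were grown in medium with 10% fetal bovine serum, and the knockdown cells carried inducible hairpins against UBE3D delivered by lentivirus, per the labels' protocols. Total RNA of 3 control and 3 knockdown libraries was depleted of ribosomal RNA, copied with random primers and sequenced as stranded read pairs of 75 bp, per the labels' protocols. The submitters' processing notes name cutadapt 1.8.1, STAR 2.5.2b, DESeq2 and the genome build hg38. The annotation, the counting tool, its strand setting, the way DoG regions were called and the scaling of each table are not given in the sources used here.

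The files hold the authors' deposited tables of 1 comparison, for 20115 genes and 2014 DoG regions, with no value per library. Per the file headers, each row has a mean normalized count over the libraries (used as a signal), a log2 fold change, its SE on the log2 scale, a p-value and an adjusted p-value, as the authors' DESeq2 step wrote them. The deposited adjusted p-values equal a Benjamini-Hochberg adjustment over the rows of each table. The deposited log2 fold changes are shrunken: divided by their SE they lie below the normal quantile of the p-value in all 20112 gene rows and 2014 DoG rows where that quantile is above 0, with a median ratio of 0.64 and 0.827. The lowest mean in the gene table is 7.74, and genes below it are not analysed here. Depth per library is unknown, and the SE is the only measure of precision. Gene and DoG tables may have been scaled separately, so levels are not compared across them.

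Genes and regions were counted as changed at a deposited adjusted p under 0.05, with the sign of the log2 fold change. The tests of the report's comparisons, the gene lists and the rule for naming genes were fixed before the data were examined. The word scan, the use of opposite-strand genes, the Wald test on unshifted values, the signed normal quantile and most tests of the closing part were chosen after values were seen. The rule took UBE3D and CPSF3; the 8 largest rises and 8 largest falls at a mean of at least 100, leaving out clone names; up to 4 members past the threshold per list by p-value, or up to 2 others where none passed; and the 8 largest rises and 4 largest falls of DoG regions at a mean of at least 50. Of the 97 genes named by it, 92 passed the threshold. Of 30 gene lists 29 had the 3 members required and were tested with cameraPR of limma 3.58.1 in R 4.3.3, on log2 fold change over SE with a preset inter-gene correlation of 0.01 against all genes, with Benjamini-Hochberg adjustment over lists. A correlation could not be estimated without values per library, so a preset of 0.05 was the alternative. Lists overlap in places, as 5 genes are both matrix genes and fibroblast markers.

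A DoG region was tied to the gene of its name, or to the sole part of a merged name found in the gene table (1920 of 2014 regions). Shares have exact Clopper-Pearson 95% intervals, which cover counting of regions only. Differences between DoG and host were divided by the root of the summed squared SE. Host medians were set against 10000 draws of expressed genes (mean of at least 10) without a changed DoG, matched on 20 classes of mean count. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. The files hold no coordinates; positions come from GENCODE 29 on GRCh38, matched by symbol for 18409 of 20115 genes, and the authors' annotation may differ from it. The 3' UTR of a gene was its longest in the basic coding transcripts (at least 50 bases), found for 9129 of 9743 genes with a mean of at least 100. In the word scan, log2 fold changes were limited to 2 either way and adjusted for 3' UTR length, GC content and mean count before the 16134 words of 7 bases present in at least 50 genes were compared. The scan was repeated in 2 random sets of genes of equal size, with the lowest word of each tested in the other set. Genes outside these rules that the text names were also chosen after their values were seen.

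The steps were tested on simulated data. A planted word ranked 1 of all words over 9129 genes, and the lowest z without one was -4.04. Of 200 regions given a DoG-to-host difference of 1 log2 unit among 1798, 94% were called, and 5.53% of calls were unchanged regions. DoG and host values were drawn independently and without shrinkage, and smaller differences were not simulated. The median absolute log2 fold change of changed DoG regions was 0.463. The 94% is therefore not the power of the test on the deposited values. On simulated statistics for 20115 genes, 60 of 60 shifted lists were called and 0 of 580 unshifted ones. These statistics were drawn independently for each gene, so the error rate for lists of correlated genes was not tested. The alternatives tried were other thresholds, minimum counts, a shift of the fold changes to a median of 0, other list statistics and subsets of regions.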

Results

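RNA of MDA-MB-231 cells, a line from a triple-negative breast cancer, was sequenced in 2 groups of 3 libraries: control cells, and cells in which doxycycline induced short hairpins against UBE3D. The series title concerns CPSF73, the endonuclease of pre-mRNA 3' end cleavage (gene CPSF3), and the migration and invasion of breast cancer cells. The design text asks which genes and which readthrough transcripts changed on UBE3D depletion. The authors' deposited tables give 1 comparison, knockdown over control, for 20115 genes and for 2014 downstream-of-gene (DoG) regions, the stretches of transcription that continue past a gene's end. The labels do not say which hairpin the control carried or whether it received doxycycline. They mark each sample as pooled and do not say that libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Counts per library were not analysed here, so sequencing depth is unknown and no value per replicate can be given. Mean normalized counts ranged from 7.74 to 135141 per gene and from 21.8 to 76002 per DoG region in the authors' deposited tables. All log2 fold changes and standard errors (SE) below are the authors' deposited values, and they are shrunken toward 0, so true folds can be larger.

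UBE3D itself, on chromosome 6 (82892398 to 83065841, GRCh38), was lower in the knockdown: in the authors' deposited table its log2 fold change was -0.80 (SE 0.37, adjusted p = 0.00632), 1.74-fold lower after shrinkage, at a mean of 36.7 normalized counts. This call was lost when the deposited shrunken change and SE were put to a Wald test (adjusted p = 0.295, and 0.327 with fold changes shifted to a median of 0). The unshifted test can only weaken calls, as shrunken changes over SE lie below the normal quantile of the p-value in every gene row compared. Its loss therefore does not by itself argue against the knockdown. CPSF3, on chromosome 2 (9423568 to 9473101), had a log2 fold change of -0.12 (SE 0.13, adjusted p = 0.464), and UBE2C, an E2 ubiquitin-conjugating enzyme, one of -0.03 (SE 0.10, adjusted p = 0.867), both from the authors' deposited table. As a list of 3, with 1 lowered here and when adjusted over the list alone, these genes did not differ from the others (cameraPR adjusted p = 0.528). Of 22 cleavage and polyadenylation factors, 19 did not pass the adjusted p threshold of 0.05 in the authors' deposited table (cameraPR adjusted p = 0.647). PAPOLA, the canonical nuclear poly(A) polymerase, fell by 1.15 on the log2 scale (SE 0.14, adjusted p = 9.11e-16). PCF11, which takes part in cleavage and in termination, rose by 0.52 (SE 0.12, adjusted p = 7.18e-06), and RBBP6 by 0.39 (SE 0.16, adjusted p = 0.0121), per the authors' deposited table. Of 14 Integrator subunits, INTS3 (log2 fold change -0.34, adjusted p = 0.00432) and INTS2 (-0.25, adjusted p = 0.0489) were lower in the authors' deposited table and the other 12 did not pass (cameraPR adjusted p = 0.647).

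More genes fell than rose. At an adjusted p under 0.05 in the authors' deposited table, 929 genes rose and 1595 fell, and 113 and 280 of these changed at least 2-fold. The largest falls among genes with a mean of at least 100 normalized counts were those of IGFN1 (13.9-fold lower, log2 fold change -3.79, SE 0.55), the adhesion receptor gene ADGRG1 (8.10-fold lower, -3.02, SE 0.23) and the matrix glycoprotein gene TNC (7.81-fold lower, -2.96, SE 0.12), per the authors' deposited table. CD109 (-2.60), LAPTM5 (-2.41), the carbonic anhydrase gene CA12 (-2.41), HLA-DRA (-2.33), which encodes the MHC class II alpha chain, and the actin-capping gene CAPZA2 (-2.29) followed in the authors' deposited table, with SE from 0.14 to 0.43. The largest rises in the authors' deposited table were those of the zinc finger gene ZNF45 (4.76-fold higher, log2 fold change 2.25, SE 0.13), C1orf220 (4.14-fold, 2.05, SE 0.16), the antiviral gene RSAD2 (4.12-fold, 2.04, SE 0.18) and ZNF699 (3.96-fold, 1.99, SE 0.19). MYO7B (1.93, SE 0.52), the tight junction gene CGN (1.78, SE 0.33), LYPD6 (1.64, SE 0.16) and SMAD6 (1.57, SE 0.20), an inhibitor of BMP signalling, completed the 8 largest rises in the authors' deposited table. Zinc finger genes and HLA-DR genes have close paralogs, so reads could be shared between copies and their values are uncertain to that extent. The 3' untranslated regions (UTRs) of CAPZA2, CD109 and the raised gene LYPD6 hold the 7-base word GATTGAA, and of 1156 lowered genes with a mean of at least 100 and an annotated 3' UTR, 320 do, against 1035 of all 9129 such genes. The share of lowered genes with the word was larger for larger falls. It was 21.2% for falls under 0.5 on the log2 scale, 32.1% from 0.5 to 1 and 40.4% (55 of 136) from 1 on. Another word, CTTATCT, goes with rises: 14.6% of the 1137 genes that hold it rose, against 6.26% of those without it. Hairpin sequences are not given in the sources used here, so whether either word belongs to a hairpin, of the knockdown or of the control, is not known. Changes leaned with abundance: the share of genes above 0 was 26.0% (95% exact interval 23.5 to 28.5) below a mean of 10, 59.0% (56.9 to 61.1) from 100 to 200 and 37.9% (35.7 to 40.0) from 1000 on, computed from the authors' deposited table.

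Genes of migration and invasion fell together, the subject of the series title. Of 30 members, 16 fell and none rose (0 raised and 19 lowered when adjusted over the list alone), and the list was lower than the other genes (cameraPR adjusted p = 1.14e-18, median log2 fold change -0.27). The stromelysin gene MMP3 fell 33.4-fold (log2 fold change -5.06, SE 0.45) at a mean of 83.6 normalized counts in the authors' deposited table. PLAU, which encodes urokinase, had -1.85 (SE 0.15), the caveolin gene CAV1 -1.68 (SE 0.15) and the collagen cross-linking enzyme gene LOX -1.20 (SE 0.12), each with an adjusted p of 5.53e-24 or less in the authors' deposited table. Of the 4 members whose 3' UTR holds GATTGAA, 3 fell, CAV1 among them. Mesenchymal genes were lower as well, with 8 of 17 lowered and 1 raised (9 and 1 when adjusted over the list alone; cameraPR adjusted p = 6.88e-09). TGFBR2, a receptor for TGF-beta, fell by 1.61 on the log2 scale (SE 0.13), the membrane protease gene MMP14 by 1.10 (SE 0.17), the fibronectin receptor gene ITGA5 by 0.93 (SE 0.09) and TGFBI by 0.88 (SE 0.13) in the authors' deposited table. Of the 3 mesenchymal members whose 3' UTR holds GATTGAA, 1 fell, TGFBR2, and 1 rose. Extracellular matrix genes went both ways. Of 26 members 9 fell and 3 rose, the same numbers when adjusted over the list alone, and the list was lower by the statistic (cameraPR adjusted p = 3.97e-08) but not by its ranks (adjusted p = 0.142). THBS1 (-1.29, SE 0.13) and LAMA3 (-0.91, SE 0.08) fell beside TNC, while the fibrillin gene FBN1 rose by 1.15 (SE 0.09), per the authors' deposited table. Of the 2 matrix members whose 3' UTR holds GATTGAA, 1 fell, THBS1, and none rose. Epithelial genes were mixed, with 6 of 22 lowered and 2 raised (8 and 3 when adjusted over the list alone; cameraPR adjusted p = 0.0909): SPINT2 (-0.98), CLDN7 (-1.11) and the desmosomal gene DSP (-0.90) fell and CGN rose in the authors' deposited table.

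Hypoxia and glycolysis genes were lower: 13 of 23 fell and none rose (20 and 0 when adjusted over the list alone; cameraPR adjusted p = 1.09e-13), and none of their 3' UTRs holds GATTGAA. NDRG1 fell by 1.05 on the log2 scale (SE 0.13), the hexokinase gene HK2 by 0.85 (SE 0.12), PFKFB3 by 0.56 (SE 0.09) and the glucose transporter gene SLC2A1 by 0.49 (SE 0.10) in the authors' deposited table. Interferon-stimulated genes were higher, with 19 of 35 raised and 1 lowered (20 and 3 when adjusted over the list alone; cameraPR adjusted p = 6.63e-14). The 3' UTRs of 7 members hold GATTGAA, and 3 of these rose, SAMD9 and OAS3 among them. RSAD2 led the list, followed by SAMD9 (log2 fold change 1.05, SE 0.12), OAS3 (0.82, SE 0.11) and DDX60 (0.61, SE 0.10) in the authors' deposited table. Cholesterol synthesis and SREBP genes were higher on balance, with 6 of 23 raised and 1 lowered (8 and 3 when adjusted over the list alone; cameraPR adjusted p = 0.00421 at the preset correlation of 0.01 and 0.0591 at 0.05). SC5D rose by 0.52 (SE 0.10), STARD4 by 0.72 (SE 0.15), HMGCS1 by 0.46 (SE 0.11) and the regulator SREBF2 by 0.37 (SE 0.09), per the authors' deposited table. Cytoplasmic ribosomal protein genes had a median log2 fold change of 0.11 (cameraPR adjusted p = 0.000202 at the preset correlation and 0.0618 at 0.05), but only 3 of 86 rose, RPL22L1 (0.38), RPS10 (0.42) and RPS12 (0.35), and RPL22 fell (-0.35) in the authors' deposited table. None passed when adjusted over the list alone, and processed pseudogenes of this family could share reads. Immediate early genes were lower at the preset correlation (cameraPR adjusted p = 0.0461) but not at 0.05 (adjusted p = 0.215). Of 24 members 7 fell and 2 rose, the same numbers when adjusted over the list alone. DUSP5 (-0.89, SE 0.11), EGR1 (-1.54, SE 0.30) and CTGF (-0.65, SE 0.13) fell and ANKRD1 rose by 1.29 (SE 0.17) in the authors' deposited table. The gene list plot sets 8 of these lists side by side.

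**Figure D1:**
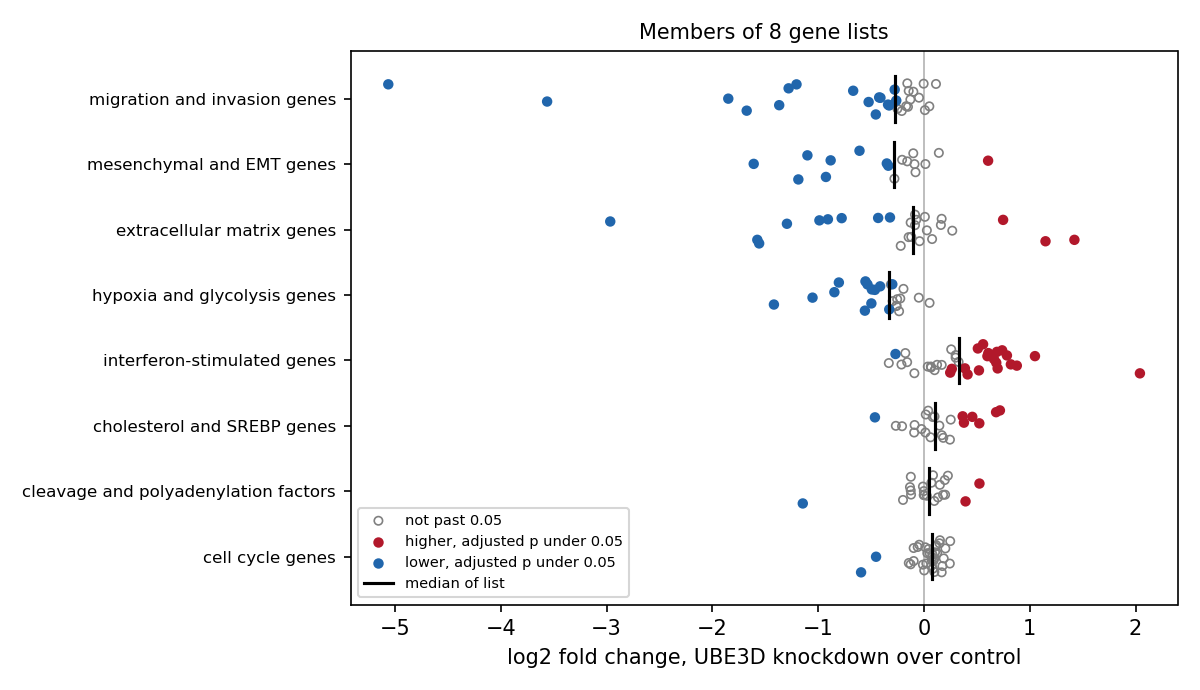
Log2 fold change of each member of 8 gene lists, UBE3D knockdown over control (x axis), with 1 row per list; filled points passed an adjusted p of 0.05 in the authors' deposited table, open points did not, and the black bar is the list median. The migration, mesenchymal and hypoxia lists have medians of -0.27, -0.28 and -0.33, and the interferon list one of 0.33.

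The remaining lists did not pass the list test. Cell cycle genes changed little, with 33 of 35 not past the threshold and E2F1 (-0.59, SE 0.14) and CCNE1 (-0.45, SE 0.16) lower in the authors' deposited table (cameraPR adjusted p = 0.343, and 0.026 on ranks, upward). Among 20 p53 target genes, CDKN1A, which encodes the cell cycle inhibitor p21, fell by 1.08 (SE 0.09), TNFRSF10B was lower (-0.27, SE 0.12), and GADD45A (0.66, SE 0.16) and TIGAR (0.40, SE 0.17) were higher, per the authors' deposited table (cameraPR adjusted p = 0.647). Of 28 stress response genes 5 fell, among them DDIT4 (-1.94, SE 0.12), TRIB3 (-0.73), EDEM1 (-0.57) and SLC7A5 (-0.43), and 3 rose in the authors' deposited table (cameraPR adjusted p = 0.343). LIF (-1.03, SE 0.16), SOD2 (-0.96, SE 0.19) and ICAM1 (-0.33, SE 0.12) were the 3 of 24 inflammatory genes that changed in the authors' deposited table (cameraPR adjusted p = 0.343). Of 22 stemness genes 5 fell, with the transporter gene ABCG2 at -1.83 (SE 0.19) and JAG1 at -0.87 (SE 0.10), and 3 rose, with the BMP-responsive genes ID3 at 1.25 (SE 0.12) and ID1 at 0.74 (SE 0.13) in the authors' deposited table (cameraPR adjusted p = 0.656). Of 15 Wnt target genes, DKK1 rose by 0.67 (SE 0.14) and LEF1 (-0.99, SE 0.59) and CCND1 (-0.28, SE 0.12) were lower, per the authors' deposited table (cameraPR adjusted p = 0.647). HSPA4L (0.45, SE 0.16) was the 1 of 16 heat shock genes past the threshold in the authors' deposited table (cameraPR adjusted p = 0.752). Adjusted over the list alone, the counts raised and lowered were 3 and 3 for p53 targets, 5 and 6 for stress response genes, and 1 and 3 for Wnt targets. They stayed the same for the cell cycle, inflammatory, stemness, heat shock, Integrator and cleavage factor lists.

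Replication-dependent histone genes, whose transcripts are also cut by CPSF73, had 11 of 55 members lowered and none raised (0 and 12 when adjusted over the list alone), while the list did not differ from other genes (cameraPR adjusted p = 0.647, and 0.000983 with log2 fold changes in place of the statistic). The lowered members were of low abundance, with a median mean count of 15.8 against 350 for the other 44. Of the 33 histone genes with a mean of at least 100, 1 fell and their median log2 fold change was 0.07. HIST1H4E (-1.78, SE 0.46), HIST1H2BI (-1.62, SE 0.48), HIST1H2BG (-1.78, SE 0.59) and HIST1H1B (-1.24, SE 0.54) were lower in the authors' deposited table, and near-identical copies make counts of single histone genes uncertain. Of 6 histone pre-mRNA processing factors, LSM11 (0.35, SE 0.15) and ZNF473 (0.25, SE 0.11) rose in the authors' deposited table (cameraPR adjusted p = 0.182). Of 9 replication-independent histone genes none passed, with H2AFX at 0.22 (adjusted p = 0.0933) and H2AFY at -0.14 (adjusted p = 0.329) in the authors' deposited table (cameraPR adjusted p = 0.554). Among 163 small nuclear and nucleolar RNA genes, RNU5F-1 (-0.82, SE 0.33) and RNU5D-1 (-0.87, SE 0.47) were lower in the authors' deposited table (cameraPR adjusted p = 0.873). Adjusted over the list alone, the numbers were 2 and 0 for the processing factors and 0 and 1 for small RNA genes. Mitochondrially encoded genes were not analysed here.

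Markers of other cell types did not move as sets. The luminal breast list had MLPH (-1.25, SE 0.15) and SPDEF (-0.73, SE 0.73) lower and ERBB3 (0.90, SE 0.18) higher among 13 members in the authors' deposited table (cameraPR adjusted p = 0.553). Of 10 fibroblast markers LUM (1.42, SE 0.31) and PDGFRB (0.96, SE 0.34) were higher in the authors' deposited table (cameraPR adjusted p = 0.151, and 0.00794 with log2 fold changes). The lysosomal gene CD68 (-1.25, SE 0.15) was the 1 of 8 blood and endothelial markers that changed in the authors' deposited table (cameraPR adjusted p = 0.186). L1CAM (-0.28, SE 0.12) was lower among 10 markers of the kidney line used for packaging virus, and MITF (0.77, SE 0.14) higher among 7 melanocytic markers, per the authors' deposited table (cameraPR adjusted p = 0.647 and 0.186). The medians of these lists and their tests had the same sign. Median, mean and test differed in sign for the p53, heat shock and small RNA lists and for the list of genes known for stress-induced DoGs, whose 13 members all missed the threshold (CDC6 at 0.25, adjusted p = 0.0789, and HSPA1A at -0.29, adjusted p = 0.102, in the authors' deposited table, with a cameraPR adjusted p of 0.92). The values of this last list are those of the genes themselves, and DoG regions of its members are not given here. Adjusted over the list alone, luminal markers had 2 raised and 5 lowered, kidney line markers 0 and 2, and the other lists of this paragraph kept their numbers.

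Readthrough regions changed in both directions. Of 2014 DoG regions, 255 rose and 325 fell at an adjusted p under 0.05 in the authors' deposited table, and 21 and 19 of these changed at least 2-fold. The share of all regions above 0 was 48.4% (95% exact interval 46.2 to 50.6), with a median log2 fold change of -0.01. The split differed with abundance and with what lies beyond the gene's end. In GENCODE 29, 912 regions had a gene of the opposite strand within 10 kb past the host's end, with a mean of at least 50 in the gene table. Of these 182 fell and 54 rose, and 37.0% (33.8 to 40.2) lay above 0. The other 1102 regions, 196 of them without coordinates, had 201 raised and 143 lowered and 57.9% (54.9 to 60.8) above 0. The regions with an opposite-strand gene are more abundant (median mean count 420 against 182), and at similar abundance, from a mean of 100 on, the falls differed less than the rises. They fell in 26.0% against 25.9% of the others from a mean of 500 on, 19.2% against 15.7% from 200 to 500, 17 of 155 against 35 of 312 from 100 to 200 and 7.58% against 3.18% below 100. They rose in 12 of 400 against 25 of 189 from 500 on, 5.15% against 23.6% from 200 to 500, 17 of 155 against 55 of 312 from 100 to 200 and 15.2% against 16.3% below 100. The share above 0 was lower for them in the 3 upper classes, 45.8% (37.8 to 54.0) against 59.9% (54.3 to 65.4) from 100 to 200, 38.1% (32.5 to 44.0) against 56.6% (51.0 to 62.1) from 200 to 500 and 27.3% (22.9 to 31.9) against 41.8% (34.7 to 49.2) from 500 on, while below 100 it was 69.7% (57.1 to 80.4) against 67.8% (62.1 to 73.3). This division and the 10 kb window were chosen after the values were seen. How the DoG table was normalized is not given in the sources used here, so a shift common to all regions would not be seen.

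The largest rises were of 2 kinds. In the first, the host gene rose with its DoG. The ZNF45 region had a log2 fold change of 1.87 (SE 0.19) beside 2.25 for the gene, the LOC283140 region 1.58 (SE 0.32) beside 1.75, and the ZNF699 region was 3.49-fold higher beside 3.96-fold for the gene in the authors' deposited tables. In the second, the DoG rose far more than its host. The region past RPL14, which encodes a ribosomal protein on chromosome 3 (40457292 to 40468587), rose by 1.90 (SE 0.13) while the gene was at 0.04 (SE 0.15, adjusted p = 0.842), per the authors' deposited tables. On the same strand within 10 kb past RPL14 start ZNF620, which rose by 0.72 (SE 0.24, adjusted p = 0.00117), and ZNF619 at 0.01, in the authors' deposited table. The region named for MIR6797 and RPS19 rose by 1.51 (SE 0.14) beside 0.27 for RPS19 (SE 0.13, adjusted p = 0.0607), and the ATPAF1 region by 1.98 (SE 0.18) beside 0.42 for the gene (SE 0.19, adjusted p = 0.0183) in the authors' deposited tables. The LIMS2 region had the largest rise (2.38, SE 0.36; gene 0.26, adjusted p = 0.159) and the RPS27 region rose by 1.37 (SE 0.26; gene 0.23, adjusted p = 0.142), but opposite-strand genes lie past both, MYO7B at 1.93 and NUP210L at 0.62, in the authors' deposited tables. Whether gene values hold reads of a facing DoG was not tested, so the rise of MYO7B could in turn come from the LIMS2 region. Among the largest falls, the regions of LINC01605 (-2.46, SE 0.20; gene -1.64), PRKAR2A (-1.84, SE 0.15; gene -1.41) and CD82 (-1.74, SE 0.20; gene -1.67) fell with their hosts, per the authors' deposited tables. The BMP6 region fell by 1.89 (SE 0.17) with the gene at 0.04 (SE 0.24, adjusted p = 0.871), and the opposite-strand gene TXNDC5 stood at -1.69 in the authors' deposited tables. The BMP6 region had a mean of 2502 normalized counts and TXNDC5 one of 102, on scales that may differ. Whether reads of TXNDC5 account for the fall of the region was not tested.

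Of the 2014 regions, 1920 could be tied to a host in the gene table. The DoG change minus the host change had a median of -0.04 and was above 0 in 43.8% of regions (95% exact interval 41.5 to 46.0). By the difference over the combined SE, with Benjamini-Hochberg adjustment over regions, 78 regions were higher than their host and 83 lower. Of the 78, 37 had a lowered host, 1 a raised host and 40 a host that did not pass the threshold. Of the 83, 29 had a raised host, 1 a lowered host and 53 a host that did not pass. A region higher than its host thus need not have risen, and one lower need not have fallen. Where no opposite-strand gene was found, 52 regions were higher than their host and 17 lower, of 1008. Of these 1008 regions, 102 had no coordinates, so a gene past the host's end could not be looked for. The DoG and host values come from the same libraries and their covariance is unknown, so the combined SE is approximate. The gene and DoG tables may also have been scaled separately, so the 0 of the DoG-minus-host difference may be offset. Shrinkage differs too: the median ratio of change over SE to the p-value's normal quantile was 0.64 for genes and 0.827 for DoG regions. Across regions, which are not independent replicates, DoG and host changes had a Pearson r of 0.446 and a Spearman rho of 0.338 (permutation p = 0.0001 for each, the smallest that 10000 permutations can give). With an opposite-strand gene past the end, r with the host was 0.184 and r with that opposite-strand gene 0.778 over the same 912 regions. Over the 1008 regions where none was found, r with the host was 0.583.

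**Figure D2:**
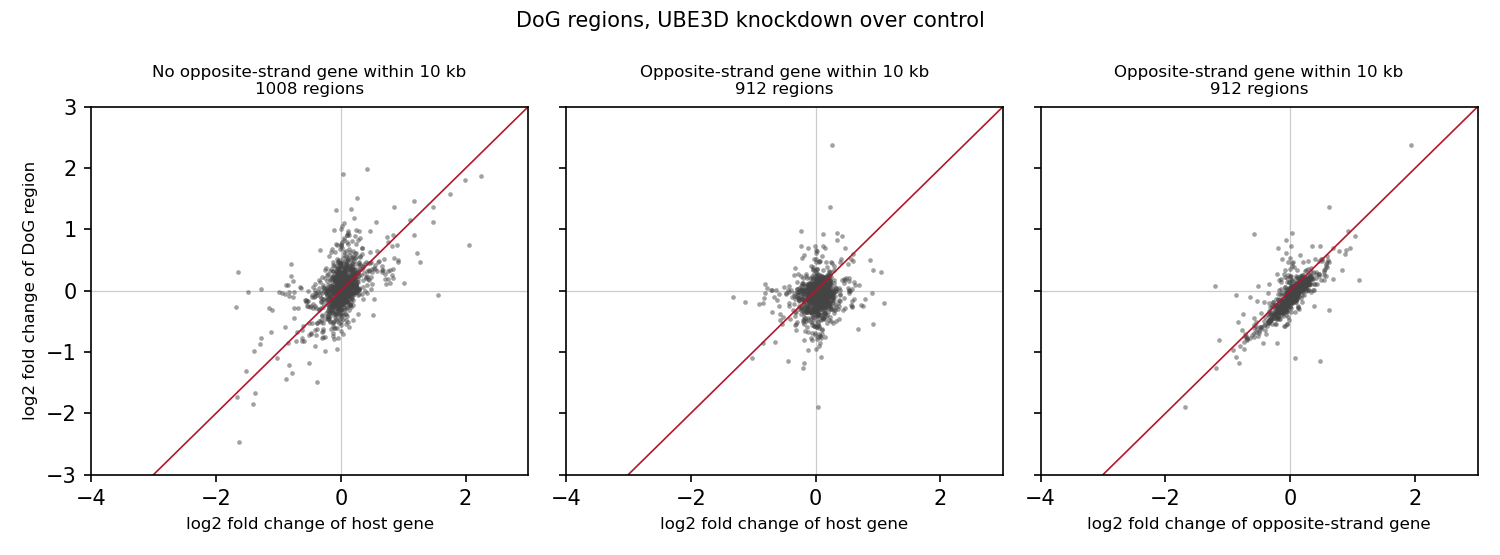
Log2 fold change of DoG regions (y axis) against that of the host gene (left and middle) or of the opposite-strand gene within 10 kb past the host's end (right), knockdown over control, 1 point per region; the red line marks equal change. Regions that face an opposite-strand gene lie along the line of that gene (r = 0.778) and not along that of the host (r = 0.184). The left panel holds the 1008 regions where no such gene was found, 102 of them without coordinates.

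Genes with a changed DoG tended to change the same way. Of 241 hosts of raised regions, 66 rose (27.4%), against 852 of 18342 expressed genes without a changed DoG (4.65%; Fisher's exact test, two-sided, odds ratio 7.74, p = 2.9e-31). Of 307 hosts of lowered regions, 62 fell (20.2%) against 1515 of those 18342 genes (8.26%; Fisher's exact test, odds ratio 2.81, p = 1.2e-10). Opposite changes were rarer for raised regions, with 5 hosts lowered (Fisher's exact test, odds ratio 0.235, p = 0.000118), and 7 hosts of lowered regions rose (Fisher's exact test, odds ratio 0.479, p = 0.053, with odds ratios from 0.156 to 0.271 and p from 0.000827 to 0.0318 under the 3 alternatives). The hosts of raised regions had a median log2 fold change of 0.14, above all 10000 draws of genes matched on mean count, whose medians reached 0.04. Hosts of lowered regions had a median of -0.06, below all draws, the lowest of which was -0.05. Most changed regions nonetheless had a host that did not pass the threshold, 170 of the 241 raised and 239 of the 308 lowered regions with a host.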

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

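The alternatives that leave out GATTGAA genes or regions facing an opposite-strand gene, the Wald test on unshifted values and the signed normal quantile were chosen after seeing the data. No paired analysis was possible because the tables hold no values per library; for the same reason edgeR, DESeq2 on counts, other scalings, the replicate block, leaving out replicates, a pseudocount, DoG-table sizes, an estimated correlation and other splits of the samples were not run. The 929 raised and 1595 lowered genes became 579 raised at an adjusted p of 0.01, and 113 and 280 with a log2 fold change of at least 1. They became 436 and 747 when fold changes were shifted by their median of -0.02 and tested with a Wald test, but that test gave 390 and 826 without a shift, so the lower counts come from the shrunken values; 23 of the 24 named genes it lost, UBE3D among them (adjusted p = 0.327), were lost without the shift too. The 255 raised and 325 lowered DoG regions became 155 raised at 0.01, 21 and 19 with a log2 fold change of at least 1, 149 and 211 under the shifted test and 141 raised under the unshifted one. Without regions facing an opposite-strand gene 143 were lowered (201 raised), so the balance changed sides: the lowered share of calls went from 56.0% to 41.6%, the share of regions above 0 from 48.4% to 57.9% and that above their host from 43.8% to 52.7%, an interval of 49.5 to 55.8 that holds 50% (17 regions lower than their host). The regions left out are more abundant, but abundance alone does not account for this, as their share above 0 was also lower at similar mean counts from 100 on. With hosts that passed no threshold, 38 regions were higher and 48 lower than the host, of fewer regions tested. All shares above or below the host depend on the relative scaling of the gene and DoG tables, which is unknown. At a preset correlation of 0.05, 1 list was higher in place of 3. Immediate early genes also missed 0.05 with log2 fold changes (0.0781), with a mean of at least 10 (0.0572) and with the normal quantile (0.057); the cause was not tested. Migration, mesenchymal, hypoxia and interferon lists passed under all 6 alternatives, without GATTGAA genes too. Leaving those genes out cannot show whether other members changed downstream of lowered genes that hold the word, such as TGFBR2. The odds ratios of same-direction host and DoG changes stayed above 1 with p under 0.05, from 5.0 (mean of at least 100) to 10.6 for rises and from 2.11 to 6.03 (without facing regions) for falls. A minimum mean of 10 and 1 region per host removed no DoG region, so they test nothing. No odds ratio, list test or named gene past its threshold changed direction. Unknown depth limits what low-count genes such as UBE3D can show.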

Other observations

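The genes of this paragraph were picked after their values were seen, and no list test was run on them. Of 15 genes with HLA-D symbols, which encode MHC class II chains and related proteins or are their pseudogenes, 7 fell and 8 did not pass the threshold in the authors' deposited table. Beside HLA-DRA, the authors' deposited table has HLA-DRB1 at a log2 fold change of -1.95 (SE 0.26), HLA-DPB1 at -1.49 (SE 0.37), HLA-DPA1 at -0.98 (SE 0.24), the invariant chain gene CD74 at -0.72 (SE 0.14) and CIITA, the transcriptional coactivator of these genes, at -1.48 (SE 0.30). The 3' UTR of CIITA holds GATTGAA, and those of the other genes of the preceding sentence do not. Whether their falls follow from that of CIITA was not tested. HLA-DMA (0.04, SE 0.14) and HLA-DMB (-0.07, SE 0.20) did not pass the threshold in the authors' deposited table. Some readthrough regions rose beside hosts that did not pass the threshold and with no opposite-strand gene found, such as those of BUB3 (1.32, SE 0.19; gene -0.08) and NUDCD1 (1.05, SE 0.18; gene 0.02) in the authors' deposited tables, also picked after seeing their values.

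All tests in the 3 patterns that follow were chosen after the result was seen, except the comparison of coding sites and the matching of zinc finger genes on abundance and 3' UTR, and the patterns themselves, with the zinc finger class and its 20 to 25 Mb window, were noticed in these data.

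Genes with GATTGAA in the 3' UTR were lowered more often, 30.9% of 1035 against 10.3% of genes without it (odds ratio 3.89). Of those with the word 5.31% were raised, against 7.55% without it, and most did not pass the threshold. The word had the lowest z of 16134 words (-17.8, the next unrelated one -4.74), after shorter and longer words had also been scanned. Base composition or length does not account for it, as 2 random sets of genes each gave the same word and its mean residual in the set not used to choose it was -0.159 or lower (95% bootstrap interval -0.198 to -0.123, lowest of 209 other arrangements of the same bases -0.0564). A site that acts equally anywhere in the transcript is argued against by the coding sites. In mean log2 fold change, genes with the word only in the coding sequence were 0.15 higher than those with it in the 3' UTR (0.12 to 0.18). They were still 0.06 lower than genes with neither (0.04 to 0.08). The coding comparison was not adjusted for 3' UTR length, GC content or mean count, so part of the 0.15 could come from these. A candidate explanation is pairing of a hairpin's seed with mature transcripts, but it was not settled: hosts with the word had DoG-minus-gene differences 0.0237 higher (-0.0401 to 0.0892) where no opposite-strand gene was found, a limit set after seeing 0.0907 (0.0316 to 0.149) over all regions, where DoG values partly follow other genes. Whether a hairpin's own target site holds the word stays open, since the UBE3D transcript has 1 copy, in the coding sequence, and 10.7% of transcripts of similar length hold the word too. A consequence of UBE3D loss for these transcripts was not tested, and the tables hold no comparison of separate hairpins to tell it from a sequence-directed effect.

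DoG regions changed beside hosts that did not pass the threshold in 409 regions. Reads of a gene on the opposite strand past the host's end may account for part of these. Over 912 regions DoG and opposite-strand gene changes had a Pearson r of 0.778 (95% interval 0.751 to 0.803), against 0.115 between host and opposite-strand gene. For same-strand genes r was 0.19 (0.061 to 0.314), over the 224 regions with such a gene. Only the nearest gene of each strand was used. Of the 239 lowered regions 69 face a lowered gene, against 10 of 1204 unchanged regions. Only 21 of the 170 raised regions face a raised gene, against 29 of 1204. Wider windows, both strands and the shares had been looked at first, and whether gene values hold reads of a facing DoG was not tested. That the host moved the same way and missed its threshold cannot be told apart for single regions, since only 22.7% differed from the host by the test. The hosts' median change in the direction of the DoG was 0.04 against 0.45 for the DoGs, a comparison added to the rule after the share was seen. Choosing called DoGs beside hosts not called favours such a gap by itself, so the gap does not decide the question. Among the 162 regions with no gene found within 10 kb, 104 rose and 58 fell (64.2% raised, 56.3 to 71.6), which is consistent with a rise of readthrough in the knockdown, the biological explanation. It stays a hypothesis, because DoG regions of low mean count lay above 0 more often whether they faced a gene or not (67.8% above 0 below a mean of 100 and 41.8% from 500 on, among those facing none) and the scaling of the table is unknown. DoG changes also lay above host changes in only 43.8% of all 1920 regions with a host. Where no opposite-strand gene was found the share was 52.7% (49.5 to 55.8), which holds 50%.

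ZNF-numbered genes were raised more often than other genes, though most did not pass the threshold. With a mean of at least 100, 91 of 311 rose and 8 fell, against 605 of 9056 other genes raised (odds ratio 5.78). Between 20 and 25 Mb of chromosome 19, 17 of 17 rose, by 0.47 to 1.48 on the log2 scale in the authors' deposited table. A gain of chromosome 19 as the whole source is argued against by the other chromosomes, where the odds ratio was 4.07 (2.78 to 5.95), and abundance, 3' UTR length and GC content by matched lists, whose medians reached 0.06 against 0.17. Loss of a repression directed by CTTATCT, the word of the highest z in the scan (7.31; odds ratio of being raised 2.56), does not account for it, as ZNF-numbered genes without the word were still 0.18 higher (0.16 to 0.20), while its source in other raised genes stays open. A local gain of the 20 to 25 Mb cluster cannot be told apart, because only 2 other genes were measured there (median 0.77), LINC01224 at 1.27 (adjusted p = 2.76e-16) and RPSAP58 at 0.27 (adjusted p = 0.15), below the lowest ZNF-numbered gene, in the authors' deposited table. Reads shared between these paralogs and a shared response to UBE3D loss were not tested.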
